A study of Mus musculus with 2 samples.

How the data were processed

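Polyadenylated RNA of 2 samples of mouse embryonic stem cells was measured by RNA sequencing. Both samples carry a Dgcr8 knockout, come from a 129/Ola background at passage 7, and are named replicates A and B in the labels. The series holds 1 group, and no wild-type library was analysed here. Per the labels' protocols, RNA was isolated with Trizol, libraries were made from total RNA with an Illumina TruSeq RNA kit and were reverse-stranded, and they were sequenced on an Illumina HiSeq2000. The labels do not say whether A and B were separate cultures, so the spread between them may be technical.

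The deposited values are whole-number counts per Ensembl gene, 1 library per file and 43629 genes in each, with no normalization by the authors. The submitters' processing notes name STAR 2.4.2a, featureCounts 1.4.5-p1 and the mm10 build, without saying which step each tool served. The annotation release, the strand setting of the counting and the treatment of reads that fit several places are not given in the sources used here. Whether strand was used was looked at in the counts. Of 290 genes whose exons lie wholly inside exons of opposite-strand genes, 114 had counts, with 41745 counts in A and 34437 in B. Of 460 genes wholly inside exons of other genes on the same strand, 52 had counts, with 2915 in A and 3621 in B. The counting setting itself remains unstated, so overlapping and antisense genes are uncertain.

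Gene names, positions, biotypes, GC content and transcript lengths came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes. Of the 43629 gene identifiers, 42548 were matched, and they held 99.8% of the counts of each library. GC content and length were those of the longest transcript of a gene.

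Library totals were 27872396 counts in A and 30327146 in B. Levels are in CPM, counts per 1000000 counts of the library total, computed here from the deposited counts, with the mean and sample SD over both libraries. Exact two-sided 95% Poisson limits were computed for each count and exact 95% Clopper-Pearson limits for shares of counts. For a count of 0 the bound given is instead the one-sided 95% limit of about 3 counts, which is 0.108 CPM in A and 0.0989 CPM in B. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

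Before the data were examined, 28 gene lists with 293 symbols in all were fixed, together with the tests and the rule for genes named in the text. That rule takes Dgcr8, the 3 members of each list with the highest mean CPM among those at 1 CPM or more in both libraries, and up to 2 members under 1 CPM in both, in list order. It also takes the 10 genes of highest mean CPM overall and, among genes that differed between replicates with a mean CPM of at least 5, the 5 largest ratios in each direction. Of the genes this rule takes, 2 are not reported here. Other genes named below were chosen after their values were seen. Of the listed symbols, Dux, Mirlet7bhg and Mir100hg had no row in the count tables.

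A list's level is the median log2(CPM + 0.5) of its members' means, set against 10000 random lists of the same size drawn from all genes with a count. Differences between list medians were set against 10000 pairs of random lists. No p-value was computed across genes, which are not replicates, and the percentiles describe these libraries.

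The replicates were compared gene by gene with an exact two-sided binomial test on both counts, given their sum and library sizes scaled by TMM (edgeR 4.0.16 in R 4.3.3). TMM factors were 1.03 for A and 0.968 for B. Genes at 1 CPM or more in either library were tested, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The test compares these libraries, not conditions. Log2 ratios of B over A, and the folds of single genes between replicates, are on the scale of log2(TMM-scaled CPM + 0.5). This scale understates the ratios of low genes. The biological coefficient of variation came from edgeR's common dispersion with an intercept-only design. List shifts are the median log2 ratio of members at 1 CPM or more in either library, with the percentile among 10000 random lists matched on mean expression in 20 bins. A list was called shifted outside the 2.5th to 97.5th percentile.

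The binomial test was tested on simulated Poisson counts of the 14583 tested genes, with 200 changed genes, 50 at each fold. These counts held no spread between libraries beyond counting noise. The test called 86.0% of genes changed 1.5-fold, 92.0% at 2.0-fold, 96.0% at 3.0-fold and 96.0% at 4.0-fold, and 12 of 14383 unchanged genes. The rates therefore hold for counting noise alone, not for the spread between these replicates. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were estimated as 0.101, 0.300 and 0.497.

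The alternatives were DESeq2 1.42.0 size factors, library totals without TMM, other filters, pseudocounts of 0.1 and 1, RPKM, Fisher's exact test, other backgrounds for random lists, and leaving out each replicate. Added after seeing the data were the thinning of B to the total of A, a scan of windows on uncorrected ratios and a correction for GC content and transcript length. The correction fitted cubic splines with 6 knots on the ranks of both properties over 12852 protein-coding genes. Similarity of transcripts was searched with blastn 2.17.0 at 95% identity over at least 200 bases. This threshold, and the windows of 8 neighbouring genes in the closing observations, were single choices made after exploring the data. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.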

Results

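The series profiled the transcriptome of mouse embryonic stem (ES) cells labelled as Dgcr8 knockout, made with a paired CRISPR/Cas9 approach. The sample titles carry further codes (KO2 and d5) that the labels do not explain, so whether they name a clone or a day of culture is not known here. Dgcr8 is the RNA-binding partner of the nuclease Drosha in the Microprocessor, which cuts primary microRNA transcripts. ES cells derive from the blastocyst and can form every tissue of the embryo. The data were polyadenylated RNA counts of 2 libraries of 1 group, replicates A and B, with 27872396 and 30327146 counts. With no wild-type library among the samples, the values describe levels in the knockout cells, not a change caused by the knockout. In all, 21830 genes had a count in A and 22107 in B, and 13372 reached 1 CPM (count per 1000000 counts of the library) in both. Values given with ± are the mean and SD over both libraries (n = 2), in CPM unless another unit is named.

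Dgcr8 (ENSMUSG00000022718, GRCm38 chromosome 16, 18253948 to 18289246, minus strand) held 1253 counts in A and 1942 in B. Its level was 45.0 CPM in A (95% Poisson interval 42.5 to 47.5) and 64.0 in B (61.2 to 66.9), or 54.5 ± 13.5. This placed it at percentile 68.5 among the genes at 1 CPM or more in both libraries. The level in B was 1.51-fold that in A (exact binomial test, adjusted p = 9.6e-31). Counts per gene do not tell which exons the reads came from, so transcripts that lack the edited part are counted with any others. The level therefore does not check the genotype given in the labels.

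The genes of the microRNA pathway, Dgcr8 among them, had a high list median. Of 16 measured members, 15 reached 1 CPM in both libraries, and the list median of 138 CPM lay above all 10000 random lists. The RNA helicases Ddx5 and Ddx17, which assist Drosha, reached 928 ± 242 and 507 ± 30.1. Ran, the GTPase that drives nuclear export of precursor microRNAs, reached 676 ± 26.3. The Argonaute gene Ago4 stayed under 1 CPM in both libraries, at 0.612 ± 0.352. Drosha exceeded Dgcr8 6.92-fold in A and 7.01-fold in B by CPM, which takes no account of transcript length.

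Transcripts that host microRNAs were present at mixed levels. Of 15 measured host or primary transcripts 10 reached 1 CPM in both libraries, with a list median of 7.64 CPM (percentile 71.5 of random lists). Mcm7, a replication helicase gene that hosts a microRNA cluster in an intron, reached 690 ± 64.2. Rian and Meg3, noncoding RNAs of an imprinted region on chromosome 12, reached 324 ± 90.8 and 261 ± 4.04. Mir155hg and Mir124-2hg lay under 1 CPM in both libraries, with 1 and 4 counts for the former and 1 and 0 for the latter, in A and B.

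Pluripotency gene lists had high medians. All 12 measured core pluripotency genes and all 14 naive pluripotency genes reached 1 CPM in both libraries, with list medians of 310 and 153 CPM, both above all 10000 random lists. Pou5f1, which encodes the transcription factor Oct4, reached 1674 ± 186, Trim28, a corepressor that silences retroviral elements, 2520 ± 108, and Tdgf1 727 ± 69.5. Among naive genes, Dppa5a reached 3009 ± 1757, Zfp42 (Rex1) 658 ± 14.4 and Esrrb 640 ± 3.38. Genes of the formative and primed states were lower, with a median of 8.52 CPM and 8 of 11 members at 1 CPM in both libraries (percentile 71.1). Within that list the DNA methyltransferases Dnmt3b and Dnmt3a were highest, at 309 ± 124 and 235 ± 54.3, followed by Zic5 at 29.1 ± 2.13. Fgf5, a marker of the primed state, had 4 counts in each library, and Sox3 had 26 in each.

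The naive median exceeded the formative and primed median by 4.08 on the log2 scale (3.88 in A and 3.86 in B). This difference fell at percentile 96.7 of random pairs of lists, inside their middle 95%. Core and naive genes together exceeded the neuroectoderm list by 7.46, mesoderm by 7.36, endoderm by 6.71, trophoblast by 6.60 and fibroblast markers by 6.59 on the log2 scale. Each of these 5 differences lay above all 10000 random pairs. The difference from endoderm was 7.51 in A and 6.06 in B. Germ cell genes were closest to the pluripotency genes, at a difference of 3.38 (percentile 94.9, 3.73 in A and 3.07 in B).

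Lineage marker lists had medians of a few CPM or less, inside the middle 95% of random lists from all genes with a count. Neuroectoderm genes had a median of 1.12 CPM (percentile 21.99), and 5 of 10 reached 1 CPM in both libraries. Tubb3 (60.1 ± 20.8), Nes (35.8 ± 1.22) and Sox1 (4.83 ± 2.5) were the highest, whereas Neurog2 had 0 counts in A and 1 in B. Of 10 mesoderm genes, median 1.00 CPM (percentile 23.98), 4 reached 1 CPM in both. Kdr (7.69 ± 1.97), Eomes (4.36 ± 0.479) and Mesp2 (3.21 ± 1.70) led that list, and T (Brachyury) and Mesp1 had 7 and 8 counts in each library. Endoderm genes had a median of 1.88 CPM (percentile 36.3; 1.13 in A and 2.56 in B), with 6 of 12 at 1 CPM in both. They were led by Lama1 (94.7 ± 67.0) and Col4a1 (38.9 ± 25.1), which encode basement membrane proteins, and by Cubn (7.91 ± 9.05). Sox17 and Foxa2 stayed at 0.403 ± 0.316 and 0.267 ± 0.276. Trophoblast genes had a median of 2.37 CPM (percentile 37.9; 2.94 in A and 1.53 in B), 5 of 10 at 1 CPM in both, led by Tfap2c (55.2 ± 30.7), Tead4 (30.6 ± 9.74) and Esx1 (12.6 ± 12.9). Elf5 and Gata3 lay at 0.135 ± 0.0892 and 0.457 ± 0.240.

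Germ cell genes were higher than those lists, with 9 of 10 at 1 CPM in both libraries and a median of 23.2 CPM (percentile 92.1). Stra8, which acts at the entry into meiosis, reached 91.1 ± 71.2, and the piRNA pathway genes Tdrd12 and Piwil2 reached 53.6 ± 10.9 and 31.0 ± 13.4. Asz1 had 2 counts in A and 1 in B. None of 7 measured genes of the 2-cell-like state, a rare state of ES cells with 2-cell-embryo transcripts, reached 1 CPM in both libraries. Their median was 0.440 CPM (percentile 18.3), or 0.682 in A and 0.198 in B. The highest members, Zscan4c and Zscan4d, chosen here after their values were seen, lay at 10.6 and 6.21 CPM in A and 0.561 and 0.890 in B, with Zfp352 at 11 and 3 counts in A and B and Tcstv1 at 0 in both.

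**Figure D1:**
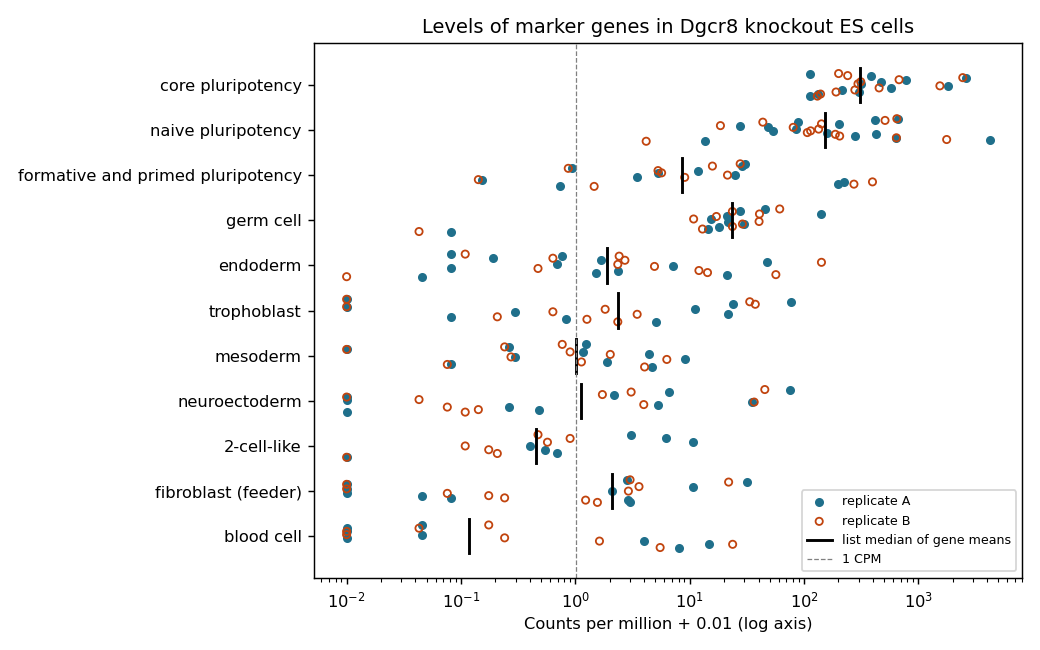
CPM plus 0.01 on a log axis for each measured gene of 11 marker lists, with filled circles for replicate A, open circles for replicate B and a black bar at the median of the gene means. Core and naive pluripotency medians lie at 310 and 153 CPM, germ cell genes at 23.2, and the endoderm, trophoblast, mesoderm, neuroectoderm, 2-cell-like, fibroblast and blood medians between 0.108 and 2.37 CPM.

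Markers of cells that could accompany an ES culture were measured as well. Fibroblast genes, which feeder cells would bring, had a median of 2.06 CPM (percentile 40.6; 2.08 in A and 1.22 in B) with 6 of 11 at 1 CPM in both libraries. Thy1 (26.7 ± 6.74), Pdgfrb (7.12 ± 4.99) and Twist1 (2.90 ± 0.143) led, and of the abundant fibroblast collagens Col1a1 held 81 counts in A and 37 in B, Col1a2 2 and 7, and Col3a1 1 and 5. Blood cell genes had a median of 0.108 CPM (percentile 2.18, and 6.06 without replicate A), or 0.0359 in A and 0.198 in B. Cd68 (19.3 ± 6.34), Cd3e (6.75 ± 1.76) and Cd79a (2.78 ± 1.65) were detected, whereas the pan-leukocyte gene Ptprc had 1 and 5 counts and Lyz2 had 0 and 1.

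Known targets of 2 groups of microRNAs were among the fixed lists. The miR-290 and miR-302 family is abundant in wild-type ES cells, whereas let-7 accumulates as cells differentiate. Of 11 miR-290 and miR-302 targets, 10 reached 1 CPM in both libraries with a median of 27.5 CPM (percentile 94.4), or 30.5 in A and 15.3 in B (percentile 85.7 without replicate A). Ei24 (263 ± 74.0), the Nodal antagonist Lefty1 (87.9 ± 104) and the cell cycle inhibitor Cdkn1a (82.3 ± 56.8) were highest, and Dkk1 had 5 and 25 counts. All 11 let-7 targets reached 1 CPM in both, with a median of 110 CPM (percentile 99.99). Igf2bp1 reached 533 ± 166, Trim71 365 ± 86.2 and Lin28a, which itself blocks let-7 maturation, 246 ± 45.2.

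Cell cycle, p53 and DNA methylation genes were expressed throughout. All 20 cell cycle genes reached 1 CPM in both libraries (median 46.7 CPM, percentile 99.85), led by Cdk4 (570 ± 13.5), Ccnd3 (373 ± 9.51) and Ccne1 (370 ± 54.8). All 8 genes of the p53 list did so as well (median 187 CPM, above all 10000 random lists), with Trp53 at 519 ± 68.8, the proapoptotic gene Bax at 275 ± 103 and Ccng1 at 245 ± 20.9. The 8 DNA methylation genes had a median of 277 CPM, above all random lists. Dnmt3l, a cofactor of the de novo methyltransferases, led with 460 ± 137, followed by Uhrf1 (427 ± 87.6) and the maintenance enzyme Dnmt1 (364 ± 67.4).

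All listed signalling components were detected. All 8 Wnt and TCF genes (median 52.5 CPM, percentile 98.8), 6 LIF and STAT3 genes (126 CPM, 99.9), 8 FGF and ERK genes (120 CPM, 99.95) and 9 Nodal and TGF-beta genes (54.0 CPM, 98.9) reached 1 CPM in both libraries. Ctnnb1, the gene of beta-catenin, reached 792 ± 173, Apc 115 ± 51.9 and Tcf7 72.1 ± 11.3. Lifr and Il6st, the receptor chains for LIF, reached 168 ± 54.2 and 134 ± 35.1, and Socs3 161 ± 20.8. In the FGF list, Fgf4 reached 245 ± 77.6 and Spry4 187 ± 74.0. Smad7 (98.7 ± 27.6), Lefty1 and Acvr1b (66.0 ± 17.0) led the Nodal list. By RPKM the Wnt and LIF lists fell to percentiles 90.2 and 97.0, and without replicate A the Nodal list to percentile 96.5. All 10 immediate early and stress genes also passed 1 CPM in both (12 CPM, percentile 79.3), with Egr1 at 236 ± 3.28, Ier2 at 110 ± 53.2 and Dusp1 at 30.2 ± 1.66.

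Interferon and innate immune genes differed widely in level. Of 14 measured, 6 reached 1 CPM in both libraries, with a list median of 0.401 CPM (percentile 7.92). Ifnb1 had 0 counts in both libraries, which allows up to 0.108 CPM in A and 0.0989 in B, and the RNA sensor gene Ifih1 had 1 count in each. Ddx58, which encodes the RNA sensor RIG-I, reached 102 ± 103, Oas1a 39.2 ± 7.39 and Mavs 38.8 ± 1.33. Imprinted genes had 14 of 15 members at 1 CPM in both libraries and a median of 61.2 CPM (percentile 99.9), and Peg10 (620 ± 482) was highest, ahead of Rian and Meg3. Of 6 sex chromosome genes, with a median of 17.7 CPM (percentile 81.55; 9.83 in A and 25.5 in B), 4 reached 1 CPM in both. The Y-linked genes Ddx3y (106 ± 61.3), Eif2s3y (55.4 ± 5.62) and Uty (25.2 ± 15.2) were detected, and Kdm5d had 6 and 3 counts.

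Glycolysis and ribosomal protein genes were the most abundant lists. All 12 glycolysis genes (median 429 CPM) and all 14 ribosomal protein genes (median 1041 CPM) lay at 1 CPM or more in both libraries, with both medians above all 10000 random lists. Pkm reached 3215 ± 541, Aldoa 2039 ± 576 and Ldha 1955 ± 451. Rpl4 reached 3911 ± 1006, Rpl8 3577 ± 1497 and Rps3 2023 ± 725. Many members of these lists have near-identical pseudogenes, to which reads of the gene can be assigned. Of 26 genes, 17 had a pseudogene match, and for 6 of them the pseudogenes held more counts than the gene in both libraries. Rps6, chosen after its values were seen, had 773 and 731 counts in A and B, against 28650 and 19217 at its 8 matching pseudogenes. Levels of such genes are uncertain.

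The 10 highest genes of all took 5.75% of the counts in A and 5.67% in B. They were the translation factor genes Eef1a1 (10398 ± 2046) and Eef2 (3772 ± 1196), the chaperone gene Hsp90ab1 (8524 ± 1267), the mitochondrial genes mt-Co1 (8444 ± 2643), mt-Nd1 (5036 ± 1053) and mt-Cytb (3943 ± 853), Ncl (4005 ± 445), Pabpc1 (3693 ± 548), Rpl4, and the noncoding Gm42418 (5389 ± 605). Mitochondrial genes made up 2.01% of counts in A (95% Clopper-Pearson interval 2.0 to 2.01) and 2.83% in B (2.83 to 2.84). Percentiles depended on the background in part of the lists. Against genes at 1 CPM or more in both libraries, the cell cycle (percentile 87.2), imprinted (96.3), Wnt (86.7) and Nodal (87.7) lists fell inside the middle 95%, the microRNA host list fell to 1.4, and the neuroectoderm, mesoderm, endoderm, trophoblast, 2-cell-like, fibroblast and innate immune lists to 0. The formative and primed (3.74), germ cell (40.2), miR-290 and miR-302 target (52.3), immediate early (10.2) and sex chromosome (27.2) lists also fell far while staying inside. Lists kept their members under 1 CPM, which this background leaves out, so a fall of lists with such members was partly fixed in advance. For the 2-cell-like, innate immune and neuroectoderm lists percentile 0 was certain. Their median log2(CPM + 0.5) lay under that of a gene at 1 CPM. Against protein-coding genes the Wnt and Nodal lists lay at 96.0 and 95.7 and the innate immune list at 0.29, or at 2.25 by RPKM.

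The replicates were then compared to measure the error of these levels. Of 14583 genes tested, 11201 (76.8%) differed between A and B, 5602 higher in B and 5599 higher in A. Of these, 5527 differed at least 1.5-fold and 2033 at least 2-fold. Without TMM the split was 4851 higher in B and 6431 higher in A, and the median log2 ratio of the tested genes was -0.10 in place of -0.01. The log2 ratio of 9537 genes at 10 CPM or more had an SD of 0.61. In simulated counts with counting noise alone it was 0.06, over 9402 unchanged genes at that level. Log2 CPM correlated between the libraries across genes with a Pearson r of 0.955, where genes are not independent replicates. The biological coefficient of variation was 0.360, or 0.219 by the median gene-wise dispersion of DESeq2. Differences of named genes below are differences between these libraries.

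Among genes with a mean of at least 5 CPM, the largest ratios of B over A on the scale of log2(TMM-scaled CPM + 0.5) were those of Gm38393 (chromosome 7, 59974149 to 60005064), 9330159F19Rik (chromosome 10), Zfp871 (chromosome 17), Gm14412 (chromosome 2, 177314520 to 177324307) and Lmbrd2 (chromosome 15). Gm38393 had 24 counts in A and 521 in B, 13.7-fold higher in B, and Lmbrd2 was 9.20-fold higher in B. All of these genes lie in the tenth of protein-coding genes with the lowest GC content, whose median log2 ratio was 0.52. Corrected for GC content and transcript length, the log2 ratio was 3.16 in place of 3.77 for Gm38393 and 2.28 in place of 3.20 for Lmbrd2. All stayed higher in B. In the other direction, Gm21761 (chromosome 13, 119912095 to 119929272) was 10.3-fold higher in A, with 525 counts against 39. Lefty1 (chromosome 1, 180935022 to 180938400) was 10.1-fold higher in A, with 4497 counts against 440. Zscan4c, a marker of the 2-cell-like state, was 9.96-fold higher in A with 295 counts against 17, Guca1a 6.90-fold and Mobp 6.74-fold.

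**Figure D2:**
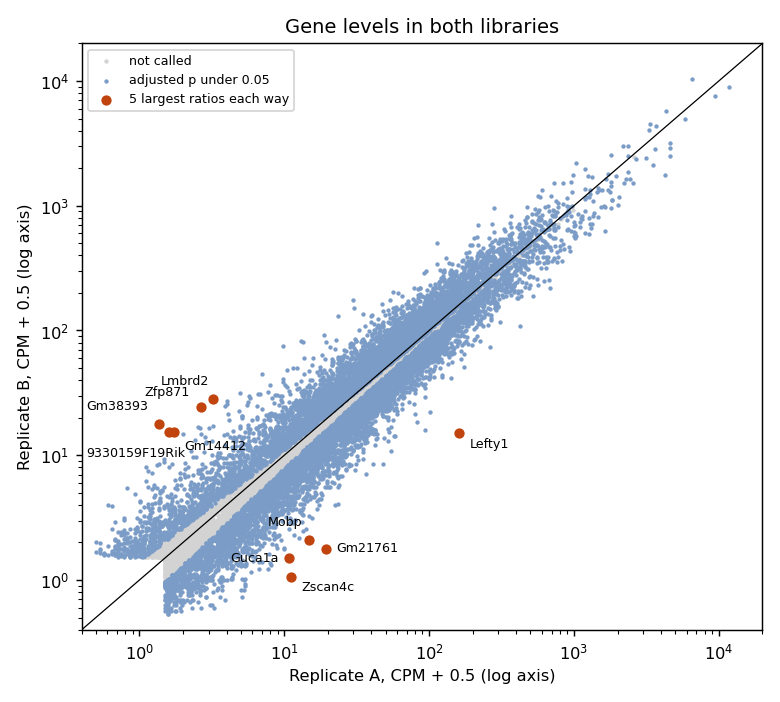
Level of each of the 14583 tested genes in replicate A (horizontal) and B (vertical), in CPM plus 0.5 on log axes, with the line of equal values. Blue points are the 11201 genes that differed by the exact binomial test, grey points those that did not, and red points the 5 largest ratios in each direction.

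Endoderm genes moved together between the libraries. Of 8 tested, 7 were higher in B and 1 was higher in A, and 8 were called when adjusted over the list alone. Gata6 and Sox7, chosen after their values were seen, lay under 1 CPM in A and passed the filter only through B. The list median was 1.41 on the log2 scale, above all 10000 random lists matched on expression. Cubn was 7.80-fold higher in B, Lama1 3.18-fold and Col4a1 2.82-fold, and Gata4, chosen after its values were seen, was higher in A (7.10 against 4.91 CPM). The 3 tested 2-cell-like genes, all of the Zscan4 family, were higher in A, with a median of -2.20 (percentile 0.045). These genes lay under 1 CPM in B and passed the filter only through A, so the filter partly set their direction. They lie in 1 region of chromosome 7, whereas random lists draw unrelated genes, so this percentile may overstate the shift.

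Naive pluripotency genes were on balance higher in A, 8 of 14 against 6 higher in B, with a median of -0.39 (percentile 0.26). Dppa5a was 2.26-fold higher in A, while Esrrb and Zfp42 were 1.07-fold and 1.03-fold higher in B, the latter being lower in B without TMM. Core genes showed no such shift, with 4 higher in B, 6 higher in A, 2 not called and a median of -0.05 (percentile 12.4). All but 1 of the DNA methylation genes, 7 of 8, were higher in B, with a median of 0.64 (percentile 98.6), and Dnmt3b and Dnmt3l were 1.91-fold and 1.64-fold higher. The sex chromosome list was higher in B (4 of 5, median 1.38, above all random lists), with Ddx3y 2.54-fold and Uty 2.60-fold higher, and Eif2s3y 1.08-fold higher in A.

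The remaining 6 shifted lists went in both directions. Ribosomal protein genes were higher in A in 12 of 14 cases (median -0.62, percentile 0.01) and glycolysis genes in 9 of 12 (-0.47, 0.12). Trophoblast genes were higher in A in 4 of 6 (-0.99, 0.14), with Esx1 5.29-fold and Tfap2c 2.13-fold higher and Tead4 1.67-fold higher in B. Nodal and TGF-beta genes were higher in A in 6 of 9 (-0.44, 1.37). The microRNA pathway was higher in B in 11 of 15 (0.62, 99.7), Ddx5 among them (1.55-fold), and let-7 targets in 10 of 11 (0.53, 98.2), with Igf2bp1 1.67-fold higher. Of these 6 lists, all but the ribosomal one were inside the middle 95% after correction for GC content and transcript length. The number of called members was the same adjusted over the list alone in each of the 28 lists. In all, 11 lists lay outside the middle 95%, where chance would give 1.4 for lists of unrelated genes. Members of a list are related, so 1.4 may be too low a reference.

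The other lists, the core pluripotency genes among them, lay inside that range. The median was 0.50 for Wnt and TCF genes, 0.49 for LIF and STAT3 genes, 0.32 for microRNA hosts, 0.28 for imprinted, 0.19 for formative and primed, 0.08 for innate immune, 0.04 for cell cycle and 0.03 for FGF and ERK genes. It was -0.05 for germ cell, -0.15 for p53, -0.15 for miR-290 and miR-302 target, -0.24 for immediate early and stress, -0.28 for neuroectoderm, -0.40 for mesoderm, -0.41 for blood cell and -0.55 for fibroblast genes. Single genes in them still differed, such as Ddx58, 6.22-fold higher in B, Peg10, 3.66-fold higher in B, Stra8, 3.23-fold higher in A, Cdkn1a, 2.71-fold higher in A, Pdgfrb, 2.57-fold higher in A, and Spry4, 1.89-fold higher in B. Of the 89 named genes that differed, Zfp42, Cdk4 and Ccnd3 changed direction without TMM and none did with DESeq2 size factors. After correction for GC content and transcript length, 11 of the 86 with a corrected value changed sign, namely Pou5f1 (-0.13 to 0.48), Thy1, Mcm7, Trp53, Bax (-0.69 to 0.24), Pkm, Aldoa, Oas1a, Tcf7, Socs3 and Ncl (0.32 to -0.38).

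The ratio between replicates followed the GC content and length of transcripts. Across 10 equal groups of protein-coding genes, the median log2 ratio of B over A went from 0.52 in the group of lowest GC content to -0.58 in the highest, and from -0.45 in the shortest to 0.56 in the longest. Both properties together accounted for 33.0% of the variance of the ratio. After correction for both, the trophoblast (-0.54, percentile 3.67), microRNA pathway (0.11, 36.5), let-7 (0.35, 94.8), glycolysis (-0.09, 2.56) and Nodal (-0.19, 5.17) lists were no longer outside the middle 95%, and the p53 list was (-0.21, 1.74). Endoderm (1.51), 2-cell-like (-2.35), naive (-0.26), ribosomal (-0.32), DNA methylation (0.60) and sex chromosome (0.65) genes stayed outside. Corrected values cover protein-coding genes, so the sex chromosome value rests on 3 of 5 tested members, of which Eif2s3y was at -0.62, and the microRNA host and imprinted lists had 1 of 10 and 10 of 15.

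**Figure D3:**
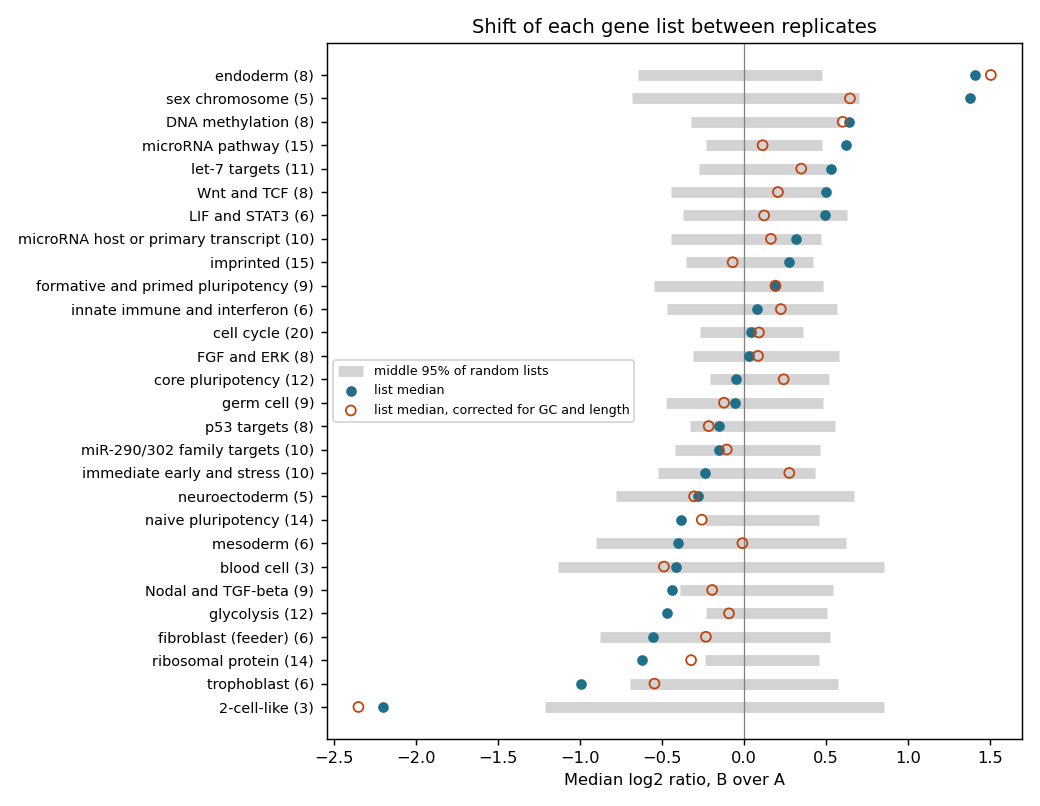
Median log2 ratio of B over A of each gene list (filled circles; tested members in brackets), the same after correction for GC content and transcript length (open circles), and the middle 95% of 10000 expression-matched random lists for the uncorrected ratio (grey bars). Endoderm genes lie at 1.41 before and 1.51 after correction, and 2-cell-like genes at -2.20 and -2.35.

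**Figure D4:**
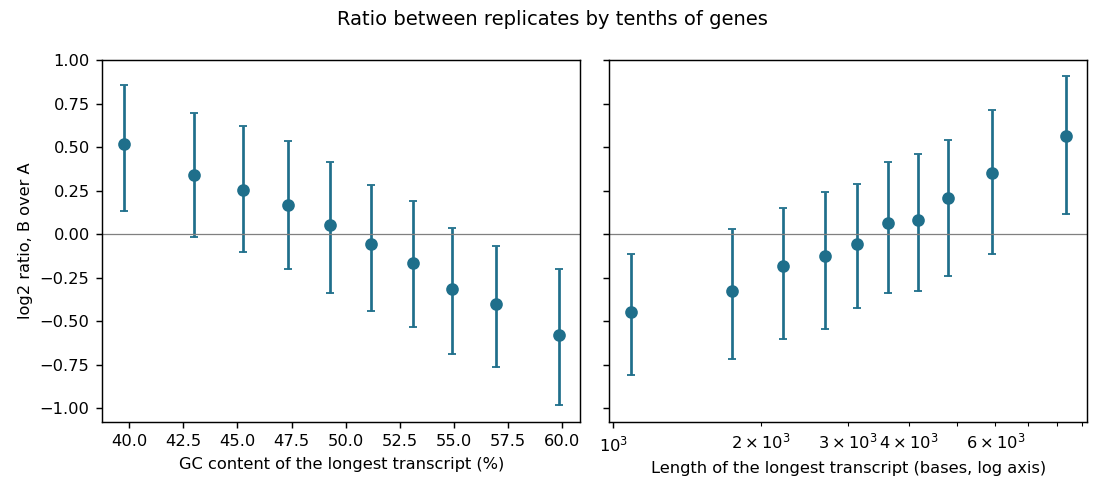
Median log2 ratio of B over A in 10 equal groups of protein-coding genes, ordered by GC content in percent (left) or by length in bases on a log axis (right) of the longest transcript, with bars from the 25th to the 75th percentile of genes. The median falls from 0.52 to -0.58 with GC content and rises from -0.45 to 0.56 with length.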

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

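The thinning of B and the correction for GC content and transcript length were chosen after seeing the data. The number of detected genes, the counts of genes that differed and the edgeR coefficient of variation stayed within 1.5 times their reported values under all scalings, filters and tests tried, except that requiring a 1.5-fold difference left 5527 genes, as fewer genes meet both criteria. DESeq2's median gene-wise dispersion gave a coefficient of 0.219, which is another summary of the genes. The correction left 2933 protein-coding genes called and 1.5-fold different in place of 4798, and 7 shifted lists in place of 11. As RPKM, a unit that divides by exon length, Dgcr8 was at 7.08. Most differences between list medians moved by more than their small spread between libraries, those from endoderm and germ cell genes excepted. Naive minus formative and primed, reported as 4.08, was 4.50 by RPKM, 4.14 and 4.0 with pseudocounts of 0.1 and 1, 3.79 by means of log2 values, and 3.86 to 3.88 leaving out either replicate. In the same order of settings, core and naive minus neuroectoderm (7.46) was 6.71, 8.09, 6.98 and 6.57, minus mesoderm (7.36) 6.07, 7.80, 6.94 and 7.24, and minus trophoblast (6.60) 5.85, 6.89, 6.32 and 6.19, with 6.66 to 6.74 leaving out either replicate. Minus fibroblast (6.59) it was 6.83 and 6.33 with the pseudocounts, 7.04 by means, and 6.81 to 6.88 leaving out either replicate. The causes were not tested. Of the list shifts under each setting, 100 kept their call and sign, 5 lost the call and 1 gained it, all 6 of these under the correction. Another 6 medians, none outside the range of random lists, changed sign: core pluripotency from -0.05 to 0.24, immediate early and stress from -0.24 to 0.28 and imprinted from 0.28 to -0.0681 under the correction, and cell cycle from 0.04 to -0.0501, innate immune from 0.08 to -0.0104 and FGF and ERK from 0.03 to -0.0634 without TMM. Of the list level percentiles, 176 kept their call and 20 did not. With 1 library left, a replicate left out gives a value with no test, so the calls between replicates could not be repeated. A count of 0 allows up to 0.108 CPM in A and 0.0989 in B, so ratios of genes near that level are imprecise. No paired analysis was possible because there is 1 group.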

Other observations

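MicroRNA genes and runs of neighbouring genes are described here, all chosen after their values were seen. Of 1899 annotated microRNA genes, 52 had at least 10 counts in both libraries. The miR-290 cluster (GRCm38 chromosome 7, 3218626 to 3220841), which gives rise to the main microRNAs of ES cells, held 9838 of 15591 microRNA-gene counts in A (63.1%, 95% Clopper-Pearson interval 62.3 to 63.9) and 6959 of 11908 in B (58.4%, 57.5 to 59.3), over 7 genes. Mir293 had 2259 counts in A and 1294 in B, and Mir290a had 842 and 969. Libraries of polyadenylated RNA do not hold mature microRNAs as such, so these counts may lie in longer transcripts. Counts per gene do not show this. Genes wholly inside same-strand exons of other genes held few counts (2915 in A and 3621 in B). MicroRNA genes so placed may be undercounted, so the share need not rank primary transcripts.

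In 5 places, medians of 8 neighbouring protein-coding genes, after correction for GC content and length, passed 1.09, the 95th percentile of the largest window over 1000 shuffles of genes. On chromosome 2 (174461072 to 178338492), 20 of 22 genes were higher in B after the correction, on which all counts of direction here rest, most of them zinc finger genes of 1 family, such as Gm14412 with 34 counts in A and 454 in B and Zfp971 with 17 and 231. On chromosome 4 (146502027 to 147585198), all 9 genes, again zinc finger genes such as Zfp978 with 260 and 2264 counts, were higher in B. On chromosome 2 (149829211 to 150668500) 6 of 10 genes were higher in B, among them Gm14124 with 99 and 816 counts. On chromosome 12 (87425840 to 91590487) 10 of 13 were higher in A, such as Gm5662 with 263 counts in A and 39 in B and Gm8332 with 136 and 12. On chromosome 7 (102557921 to 105482300) 9 of 10 were higher in A. They included Usp17la with 77 and 3 counts and Usp17lc with 60 and 3, while Trim6 had 3527 and 7843. Of those 9, Fam160a2 (970 and 1475 counts) was higher in A only after the correction (log2 ratio 0.57 before and -0.03 after), and Trim21 was not called. The summed TMM-scaled level of this run was 1.82-fold higher in B. Gm21761, with 525 and 39 counts, lies beside the 2-cell-like gene Tcstv1 (chromosome 13, 119893388 to 119894785). Corrected medians over whole chromosomes stayed between -0.05 and 0.08 for the 20 chromosomes with at least 100 genes.

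The explanations below were set up after these patterns had been noticed, and all but the thinning of B and the test of chance clustering were chosen after the result was seen. Trends with expression level and other gene families grouped by name, such as histone and proteasome genes, were also looked at before these patterns were picked. The design gives 1 group, so no biological explanation tied to a group was tested.

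The replicates differed in 11201 of 14583 genes. The test and the log2 ratios already take library size into account, so a difference in depth that acts on all genes alike is removed. Thinning B to the total of A left 11128 genes. GC content and transcript length accounted for 33.0% of the variance of the log2 ratio of protein-coding genes. For the reason given, neither value bears on depth. After the correction 7 fixed lists stayed or came outside the middle 95% of random lists, where chance would give 1.4. That value holds for lists of unrelated genes, whereas listed genes are related, so this count alone does not decide. The endoderm (1.41 to 1.51) and 2-cell-like (-2.20 to -2.35) medians did not shrink. For these lists this argues against GC content and length as the whole cause. The correction used the longest annotated transcript, so part of such a trend may remain, and the SD of the ratio at 10 CPM or more went from 0.60 to 0.47. The 2-cell-like median rests on 3 Zscan4 genes in 1 region of chromosome 7. They are not independent members and passed the filter of the test only through A. Library preparation, RNA quality and culture state may each contribute and were not tested.

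Chance order of unrelated genes is argued against most strongly for the chromosome 12 run and the larger chromosome 2 run. There 0 of 1000 shuffles gave windows as large as 2.38 and 1.82. For the runs on chromosome 4 (1.30), the smaller on chromosome 2 (1.20) and on chromosome 7 (-1.17), 4, 14 and 17 shuffles did. Shuffles treat genes as independent, whereas neighbouring copies of 1 family may share reads and low levels. On chromosome 12, Gm4027, Gm2016, Gm2035, Gm8332 and Gm5039 lay under 1 CPM in B and passed the filter only through A. The same holds for the Usp17-like genes on chromosome 7. A scan of the uncorrected ratios also gave the larger chromosome 2 run, whose median went from 1.74 to 1.62 with the correction, which argues against GC content and length as its whole cause; that scan did not give the chromosome 7 run and gave another on chromosome 5 (77349240 to 88556090). Reads split between near-identical copies stay open: 11 such copies in the larger chromosome 2 run and their matches, 43 genes in all, summed to a 3.19-fold higher level in B, but the 11 hold 693 of 717 counts in A and 2277 of 2331 in B, so the sum repeats the genes picked, reads that fit several places may have been discarded, and a first version of the test over the whole interval had given 1.4. For the runs on chromosomes 7 and 12, whose Usp17-like and other multicopy families are known from 2-cell embryos, more 2-cell-like cells in replicate A is a candidate explanation. The members of the fixed 2-cell-like list under the filter of the test, Zfp352, Tcstv3 and Tdpoz4, held 45 counts in A and 14 in B, a ratio of 3.28 (95% interval 1.77 to 6.47), and Tcstv1 had 0 in both, but these genes are near the floor and split reads were not tested there.

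Endoderm genes were higher in B. GC content and transcript length are argued against as the whole cause, since the corrected list median was 1.51, above all random lists. More endoderm-like cells in B may be a source, but this cannot be told apart from a change in single genes. After the correction 6 of 8 tested members were at least 1.5-fold higher in B. The bounds of 7 for and 4 against more endoderm-like cells were chosen after the values were seen, so this number does not decide. Gata6 (19 counts in A and 71 in B), Sox7 (21 and 73) and Dab2 (66 and 365) went with it, the first 2 passing the filter of the test only through B. Sox17 (5 and 19) and Foxa2 (2 and 14) had more counts in B but lay under 1 CPM in both libraries and were not tested. Gata4 (7.10 CPM in A and 4.91 in B) did not go with it. Pdgfra (46 and 82 counts) was higher in B but under 1.5-fold after the correction, at a log2 ratio of 0.27. Afp and Ttr, abundant in visceral endoderm, had 1 and 2 counts in A and 0 and 3 in B. Of the 12 listed genes 6 reached 1 CPM in both libraries, so ES cells themselves may express part of the list.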
